A study of Rattus norvegicus with 20 samples.

How the data were processed

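Gene expression was measured in liver of male Sprague-Dawley rats with an Affymetrix rat array that reads the 3′ end of messenger RNAs. Per the labels, rats were 4 weeks old on arrival, adapted for 5 days and then ate 1 of 4 diets for 21 days. The labels give 7, 7, 7 and 8 rats for the 4 diets, of which 5 per diet with an average food intake went onto arrays, so the 20 arrays are 20 separate rats. Each array was placed in its diet group from its title, and the titles were matched to the diet descriptions by their wording, since the labels do not pair the titles with the diet codes. Total RNA was extracted with acid guanidinium thiocyanate, phenol and chloroform and labelled with a 3′ in vitro transcription kit, per the labels' protocols. The hour of sampling and whether the rats had been fasted are not given in the sources used here.

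The authors deposited 1 value table for all 20 arrays, and per the labels the values had been normalized with the SuperNORM data service, whose version is not given in the sources used here. How the probes of a probe set were summarized into 1 value is not given in the sources used here either. The deposited values were taken as log10 of the signal, a base inferred from the files, since no label states it: on the spike-in controls of known relative amount the slope was 0.998 log10 units per log10 unit (SD 0.0236, 20 arrays). Every deposited log10 value was multiplied by 3.3219 to give the log2 values used here, so a difference of 1 on the log2 scale is a 2-fold difference. No further normalization was applied for the values in the report. Depth does not apply to arrays, and the number of arrays limits the precision.

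The table held 31099 probe sets. The 57 control probe sets and 3342 probe sets with no value on any array (1680 of them with 1 gene symbol) were left out, 2 being in both groups, which left 27702. Gene symbols came from the platform annotation: 19157 of the tested probe sets had 1 symbol, 394 had several and 8151 had none listed. No gene was named from a probe set with several symbols. The 27702 probe sets covered 13468 genes. For statements on genes and gene lists, each gene was represented by its probe set with the highest mean over the 20 arrays. Other probe sets of a named gene are given in the text where they went the other way. No array pair held identical values, and no genome build is given for the arrays, so positions are not printed.

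Differences between diets were tested with limma 3.58.1 in R 4.3.3: 1 mean per diet, fitted over all 20 arrays so that the 4 groups share 1 estimate of the spread, with eBayes and a trend of the spread with the mean level, two-sided. Benjamini-Hochberg adjustment ran over the 27702 probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Each printed standard error (SE) of a gene's difference is from this fit, with the spread that eBayes moderates. Each adjusted p of a gene is from this fit unless another setting is named. The SE of a difference in a list's mean level is from the spread between the arrays of the groups compared, without eBayes. The comparisons were each soybean diet against casein, the 2 soybean cultivars at the same share of protein, the 2 shares of the high-isoflavone soybean, and the departure from a straight line over the share of high-isoflavone soybean.

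Gene lists were tested with camera from limma, which asks whether the genes of a list shift relative to the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The same test with a correlation estimated for each list gives the second adjusted p. The rotation test fry asks whether the genes of a list move, on balance, in 1 direction, or change in either direction, and does not compare the list with other genes. Of 30 lists, 28 had at least 4 measured genes. They were lipogenesis, fatty acid oxidation and ketogenesis, cholesterol synthesis and uptake, bile acid synthesis and sterol export, lipoproteins, amino acid breakdown and urea cycle, amino acid response, glucose metabolism, targets of the receptors PXR and CAR, targets of the receptor AhR, targets of the antioxidant factor NRF2, male-predominant and female-predominant liver genes, the growth hormone and IGF axis, the circadian clock, the acute phase response, the interferon response, the cell cycle, the endoplasmic reticulum stress response, and genes of the pericentral and the periportal zones. The others were markers of macrophages, endothelial cells, stellate cells, bile duct cells, lymphocytes, neutrophils and pancreas. Lists of red blood cell and adipose markers had fewer than 4 measured genes and were not tested. Of the 520 symbols in the lists, 445 matched a tested gene, 1 of them through a synonym.

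The groups, the tests, the gene lists, the rule for named genes and the first group of alternatives given in the last paragraph were fixed before the data were examined. By that rule the named genes of a comparison are the 10 largest rises and the 10 largest falls among called probe sets with 1 informative gene symbol, the highest-mean probe set of the gene, a mean above log2 2.06, and no overlap between the 5 rats of one diet and the 5 of the other. In addition, up to 4 called members of each list are named, or up to 2 members as values where none was called. Where no probe set passed, 5 genes with the smallest p are given as values. Outside this rule, 7 genes were named after their values were seen: Gpam, Eprs1, Cox6c, Atp5mk, Cetn3, Rpl26 and Eml4. Only part of the genes that the rule allows is printed.

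The whole procedure was tested on simulated data with the same 27702 probe sets, where 200 probe sets had been changed by 1.5, 2 or 4-fold. For conventional soybean against casein, 37.3% of the probe sets changed by 1.5-fold were recovered, 89.6% of those changed by 2-fold and 98.5% of those changed by 4-fold. The same shares were 41.8%, 74.6% and 97% for the 3:1 high-isoflavone diet against casein, and 44.8%, 82.1% and 97% for the 1:1 high-isoflavone diet against casein. They were 53.7%, 70.1% and 100% for the high-isoflavone against the conventional soybean, and 47.8%, 85.1% and 98.5% for the 2 shares of high-isoflavone soybean. The simulated comparisons gave between 8 and 13 false calls each. In simulated data on 13468 genes and 28 lists, the list that had been shifted was found in each of the 5 comparisons, with 1 further list called for conventional soybean against casein. The simulated noise was drawn independently for each probe set. The simulation therefore does not show how often the list test makes false calls where genes move together.

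The alternatives fixed then were the replicate number of the labels as a block, quantile normalization between arrays, centring and scaling of each array to 1 median and 1 median absolute deviation, leaving out the dimmest probe sets (those with a mean below log2 2.06, or below 2.48), eBayes without the trend or with robust estimation, only the arrays of the groups compared, array weights, a minimum difference of 1.5-fold, and leaving out each array in turn. For the lists they were the estimated correlation, fry and the mean of all probe sets of a gene. For the overlap between comparisons the casein arrays were split. After the data had been seen, 3 alternatives were added: leaving out the 2 arrays with a higher floor, leaving out number 1 of all 4 groups, and a term for number 1. Figures were drawn with matplotlib 3.10.9 and tables were joined with pandas 2.3.3 in Python 3.11.15.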

Results

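Messenger RNA levels were measured in the livers of 20 male rats after 21 days on 1 of 4 diets, 5 rats per diet. The control diet held casein, the main protein of milk, at 200 g per kg. In the conventional soybean diet casein and a conventional soybean cultivar gave protein in equal parts. In the 1:1 high-isoflavone diet casein and a soybean cultivar rich in isoflavones gave protein in equal parts, and in the 3:1 high-isoflavone diet they gave 3 parts and 1 part. Isoflavones are plant compounds of soybean that bind estrogen receptors. The question stated by the series is what dietary soybeans and their isoflavone content do to messenger RNAs of the liver. Values are log2 signals with 5 separate rats per group (n = 5), and the number of arrays limits the precision. The ratio of 3′ to 5′ signal of beta-actin, a mark of RNA integrity, was 1.45 ± 0.103 on casein, 1.60 ± 0.202 on conventional soybean, 1.61 ± 0.302 on the 3:1 and 1.43 ± 0.395 on the 1:1 high-isoflavone diet (log2, mean ± SD). The same measure of GAPDH was 0.924 ± 0.0813, 0.822 ± 0.0812, 0.928 ± 0.0513 and 0.867 ± 0.0463. Casein replicate 5 and replicate 1 of the 3:1 high-isoflavone diet had a higher floor of the signal, at 0.134 and 0.142 log10, against at most -0.265 on the other 18 arrays. Settings without these 2 arrays, or without number 1 of all 4 groups, were added after seeing the data.

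The first comparison asked what the conventional soybean diet did relative to casein. Of 22 measured genes of fat synthesis 12 fell and 1 rose, and of 20 of cholesterol synthesis and uptake 6 fell. Each of these lists was called lower, with adjusted p = 0.108 with an estimated correlation. Fads2, the fatty acid desaturase that starts the making of long polyunsaturated fatty acids, fell by 1.39 on the log2 scale (SE 0.206, n = 5 per diet, adjusted p = 0.00185), from 7.13 ± 0.219 on casein to 5.74 ± 0.405. Pnpla3, a lipid droplet protein acting on triglycerides, fell by 3.69 (SE 0.944, adjusted p = 0.0493), from 8.17 ± 0.563 to 4.48 ± 2.23, and its other 2 probe sets fell too. The call for Pnpla3 ended in 16 of the 20 omissions of a single array, with an adjusted p of up to 0.111, and in further settings, at up to 0.121 without the 2 higher-floor arrays. Car3, a carbonic anhydrase of muscle and liver, rose 2.24-fold (SE 0.165 log2, adjusted p = 0.00154).

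Of the 22 measured lipogenesis genes, 12 fell, 1 rose and 9 did not pass. Adjusted over the list alone, 18 fell and 1 rose. The median difference was -0.89, 20 of the 22 lay below 0, and the list was lower with an adjusted p of 1.86e-19. That adjusted p = 0.108 with an estimated correlation. Besides Fads2 and Pnpla3, Fads1, a second desaturase, fell by 1.01 (SE 0.175, adjusted p = 0.00637), Pgd, which makes NADPH, fell by 1.26 (SE 0.204, adjusted p = 0.00342), and Acacb, an acetyl-CoA carboxylase, fell by 0.80 (SE 0.126, adjusted p = 0.00317). The 1 member that rose was Gpam, the enzyme that attaches the first fatty acid to glycerol phosphate. Its highest-mean probe set rose by 0.99 (SE 0.248, adjusted p = 0.0455) while the other probe set differed by -0.46 (adjusted p = 0.372), and the call ended in 11 of the 20 omissions of a single array, with an adjusted p of up to 0.108, and in further settings, among them centring and scaling (0.0637). Elovl2, an elongase of polyunsaturated fatty acids, fell by 1.40 (SE 0.255, adjusted p = 0.00809).

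Of the 20 cholesterol genes, 6 fell and 14 did not pass, and 13 fell adjusted over the list alone. All 20 differences were below 0, the median was -0.53, and the list was lower (adjusted p = 1.64e-13). The adjusted p = 0.108 with an estimated correlation. Sc5d, a late enzyme of cholesterol synthesis, fell by 0.68 (SE 0.121, adjusted p = 0.00722). Pmvk, which phosphorylates phosphomevalonate, fell by 0.84 (SE 0.17, adjusted p = 0.0162), a call that ended without casein replicate 5 (adjusted p = 0.0557) or conventional soybean replicate 3 (0.05). Fdps, which makes farnesyl diphosphate, fell by 0.78 (SE 0.168, adjusted p = 0.0230), and lost its call without casein replicate 3 (adjusted p = 0.0505), 4 (0.0547) or 5 (0.0628) or conventional soybean replicate 3 (0.0588). Without the 2 higher-floor arrays the calls of Pmvk (adjusted p = 0.0633) and Fdps (0.0691) ended too.

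Fatty acid oxidation genes were also lower as a list: 1 of 29 fell, 8 fell adjusted over the list alone, 23 of the 29 lay below 0 and the median was -0.27 (adjusted p = 5.33e-07). The adjusted p = 0.363 with an estimated correlation. The member that fell was Cyp4a1, a fatty acid omega-hydroxylase, by 0.77 (SE 0.185, adjusted p = 0.0388). Its call ended in 7 of the 20 omissions of a single array, with an adjusted p of up to 0.099. In the amino acid response list 2 of 24 fell, also 2 adjusted over the list alone, with a median of -0.16 (adjusted p = 0.00216). The adjusted p = 0.300 with an estimated correlation. Aldh1l2, a mitochondrial folate enzyme, fell by 0.59 (SE 0.119, adjusted p = 0.0162), which ended without casein replicate 5 (adjusted p = 0.0573). Atf5, a stress transcription factor, fell by 0.39 (SE 0.0876, adjusted p = 0.0257), a call that ended in 6 of the 20 omissions of a single array, with an adjusted p of up to 0.0793. Without the 2 higher-floor arrays all 3 of these calls ended, at adjusted p = 0.108 for Cyp4a1, 0.0647 for Aldh1l2 and 0.0902 for Atf5, and without number 1 of all groups those of Aldh1l2 (0.0741) and Atf5 (0.0802). With only the compared arrays, the calls of Cyp4a1 (0.0508) and Atf5 (0.0572) ended, and without the trend that of Cyp4a1 (0.0557).

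Liver genes that are higher in male rats rose as a list: 3 of 9 rose and 6 did not pass, 5 rose adjusted over the list alone, and the median was 0.54 (adjusted p = 0.00644). The adjusted p = 0.363 with an estimated correlation. Mup5, a major urinary protein, rose 1.63-fold (SE 0.135 log2, adjusted p = 0.0120), and Cyp2c13, a male-specific cytochrome P450, rose 1.45-fold (SE 0.13, adjusted p = 0.0395). The call for Cyp2c13 ended in 8 of the 20 omissions of a single array, with an adjusted p of up to 0.102. Centring and scaling ended the calls of Mup5 (adjusted p = 0.0666) and Cyp2c13 (0.186), as did leaving out the 2 higher-floor arrays (0.053 and 0.107), and Cyp2c13 lost its call in further settings. Lists of detoxification genes were not called as wholes, although single members were. Of 15 PXR and CAR targets 2 rose, or 4 rose and 1 fell adjusted over the list alone (adjusted p of the list 0.623), among them Cyp3a23-3a1, a drug-metabolizing P450, 1.75-fold (SE 0.162 log2, adjusted p = 0.0160; 0.0551 without casein replicate 5). Of 19 NRF2 targets 1 rose, or 3 adjusted over the list alone (adjusted p of the list 0.0970), namely Gclm, a subunit of the enzyme that starts glutathione synthesis, 1.83-fold (SE 0.183 log2, adjusted p = 0.0198). Cyp3a23-3a1 lost its call after centring and scaling (adjusted p = 0.0506), and both genes lost theirs without the 2 higher-floor arrays (0.0633 for Cyp3a23-3a1 and 0.05 for Gclm) and without number 1 of all groups (0.0684 and 0.0701).

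The largest rises with 5 rats of each diet not overlapping included Gdf11, a growth factor of the TGF-beta family, 4.59-fold (SE 0.362 log2, adjusted p = 0.00406), Edil3, a secreted integrin ligand, 2.95-fold (SE 0.287, adjusted p = 0.00809), and Kcna5, a potassium channel, 2.73-fold (SE 0.235, adjusted p = 0.00356). Myo16, an unconventional myosin, rose 4.15-fold (SE 0.324, adjusted p = 0.00317), while another probe set of the gene differed by -0.11. Mt2A, a metallothionein, rose 4.22-fold (SE 0.527, adjusted p = 0.0486), a call that ended in 16 of the 20 omissions of a single array, with an adjusted p of up to 0.117, and in further settings, among them quantile normalization (0.0532). Among the falls, Fabp2, a fatty acid binding protein, fell by 1.43 (SE 0.181, adjusted p = 0.000879), Ddhd1, a phospholipase, by 1.72 (SE 0.232, adjusted p = 0.00126), Wfdc21 by 1.78 (SE 0.252, adjusted p = 0.00154) and Sult4a1, a sulfotransferase, by 1.44 (SE 0.211, adjusted p = 0.00174). Lipc, hepatic lipase, fell by 0.58 (SE 0.109, adjusted p = 0.0102).

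In limma's test 453 of 27702 probe sets passed, 281 higher and 172 lower, with a median size of 0.64, and 4665 had an unadjusted p under 0.05. The 5 rats of one diet did not overlap the 5 of the other in 1279 probe sets, 4.62%, where chance gives 0.794%. The array medians did not overlap either, at 2.434 to 2.491 on casein and 2.51 to 2.562 on conventional soybean (log2). The share by chance does not allow for such a shift of whole arrays, which can itself separate the rats. The balance of rises and falls depended on the scaling of the arrays: 62% of the calls were higher as deposited, against 194 higher and 354 lower (35.4% higher) after quantile normalization and 158 higher and 472 lower (25.1%) after centring and scaling, although no called probe set changed sign. The count also depended on single arrays. It was 190, 225, 282 and 120 without casein replicates 2, 3, 4 and 5, and 294, 200, 283 and 182 without conventional soybean replicates 2, 3, 4 and 5. Without the 2 arrays with a higher floor, a choice made after seeing the data, it was 114.

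The next comparison asked the same of the 1:1 high-isoflavone diet, which held as much soybean protein as the conventional diet. Pnpla3 was again the gene with the largest fall: it fell by 5.04 on the log2 scale (SE 0.944, n = 5 per diet, adjusted p = 0.00647), from 8.17 ± 0.563 on casein to 3.13 ± 1.68. Elovl6, the elongase that makes stearate from palmitate, fell by 2.59 (SE 0.475, adjusted p = 0.00548), and Pmvk fell by 1.43 (SE 0.17, adjusted p = 0.000138). Among genes that rose, Gclm rose 2.28-fold (SE 0.183 log2, adjusted p = 0.00116) and Ugp2, which makes UDP-glucose, 2.37-fold (SE 0.233, adjusted p = 0.00647). All 5 rats on the high-isoflavone diet lay beyond all 5 on casein for each of Pnpla3, Elovl6, Gclm and Ugp2.

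Of the 22 lipogenesis genes, 13 fell and 9 did not pass. Adjusted over the list alone, 19 fell and 1 rose. The median difference was -0.97 and the list was lower (adjusted p = 9.82e-20). The adjusted p = 0.0764 with an estimated correlation. Acss2, which activates acetate, fell by 1.17 (SE 0.176, adjusted p = 0.000947), Acacb by 0.89 (SE 0.126, adjusted p = 0.000618) and Pgd by 1.33 (SE 0.204, adjusted p = 0.00116). Of the 20 cholesterol genes, 9 fell and 11 did not pass, 12 fell adjusted over the list alone, and all 20 differences were below 0 with a median of -0.51 (adjusted p = 1.21e-15). The adjusted p = 0.0764 with an estimated correlation. Lss, which closes the sterol rings, fell by 1.49 (SE 0.294, adjusted p = 0.00926), Cyp51, the next enzyme, by 0.58 (SE 0.114, adjusted p = 0.00875) and Tm7sf2, a sterol reductase, by 0.93 (SE 0.175, adjusted p = 0.00674). Beside these lists, the markers of macrophages were lower: none of the 12 passed alone, 1 fell adjusted over the list alone, 11 of 12 lay below 0 and the median was -0.30 (adjusted p = 0.00112). The adjusted p = 0.674 with an estimated correlation. Clec4f, a receptor of Kupffer cells, differed by -0.50 (SE 0.154, adjusted p = 0.0937).

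**Figure D1:**
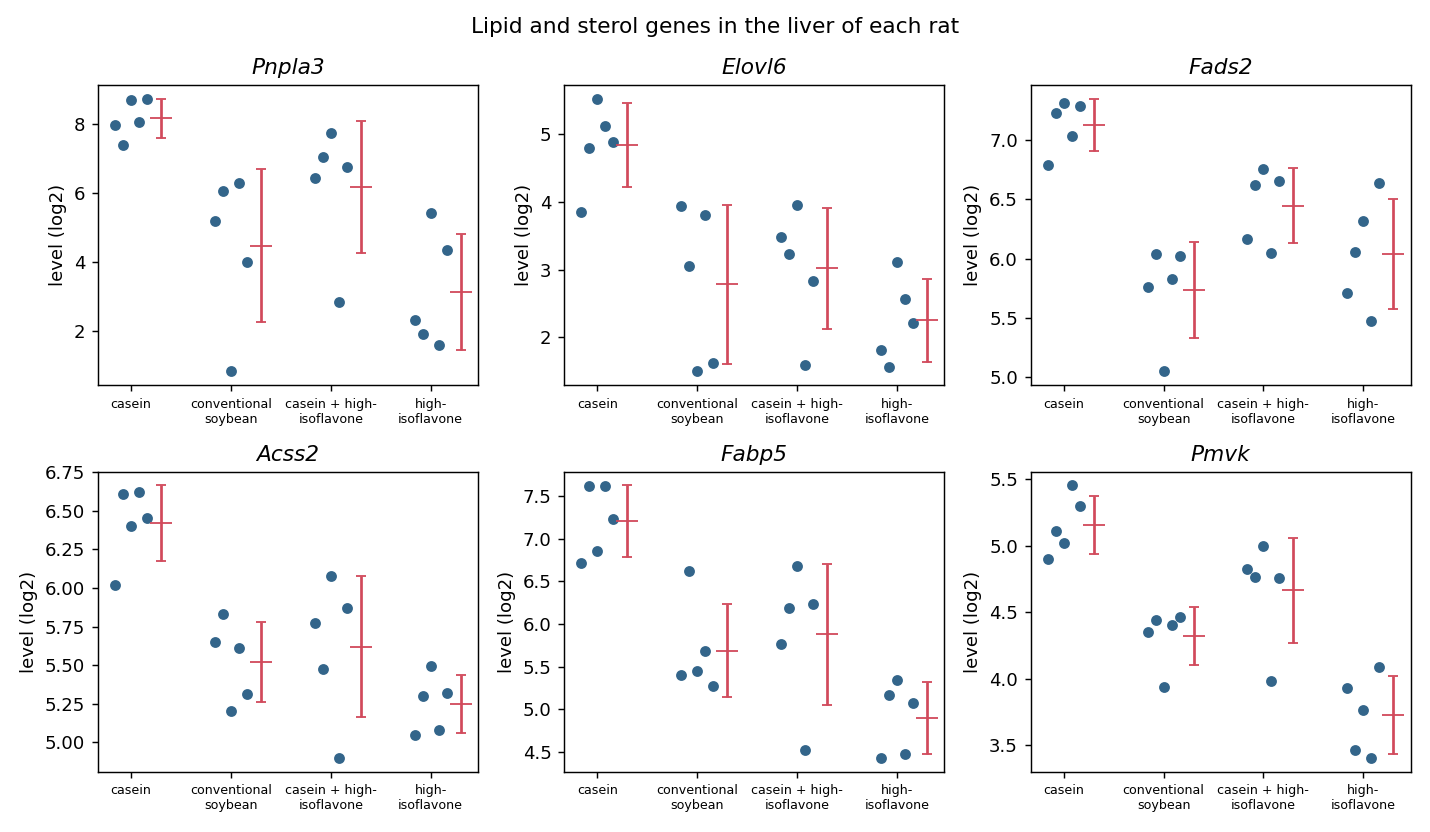
Levels of 6 genes of lipid metabolism in liver (vertical axis, log2 signal) for the 4 diets (horizontal axis). Each dot is 1 rat, the red marks are the mean ± SD of 5 rats, and Pnpla3 went from 8.17 on casein to 4.48 on conventional soybean and 3.13 on the 1:1 high-isoflavone diet.

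On the 1:1 high-isoflavone diet PXR and CAR targets were higher as a list. Of the 15, 3 rose and 12 did not pass, also 3 adjusted over the list alone, 13 lay above 0 and the median was 0.12 (adjusted p = 0.0431). The adjusted p = 0.266 with an estimated correlation. The list lost its call without casein replicate 1 (adjusted p = 0.113), 4 (0.0729) or 5 (0.0607), without replicate 1 of the 3:1 diet (0.0503), without high-isoflavone replicate 2 (0.0533), 3 (0.0589), 4 (0.0634) or 5 (0.153), and without the dimmest probe sets (0.0715). Cyp3a23-3a1 rose 1.73-fold (SE 0.162 log2, adjusted p = 0.0119; 0.0599 after centring and scaling). The mRNA of CAR itself, Nr1i3, rose 2.30-fold (SE 0.282, adjusted p = 0.0250), a call that ended in 5 of the 20 omissions of a single array, with an adjusted p of up to 0.0735, and without number 1 of all groups (0.109). NRF2 targets were not called as a list (1 of 19 up and 1 down, 2 up and 1 down adjusted over the list alone, adjusted p = 0.246). Slco1a4, a carrier of organic anions, rose 2.55-fold (SE 0.308, adjusted p = 0.0214), and lost its call without casein replicate 4 (adjusted p = 0.0653) or 5 (0.0668), high-isoflavone replicate 4 (0.0579) or the 2 higher-floor arrays (0.0745).

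Male-predominant genes were higher: 3 of 9 rose and 6 did not pass, 5 rose and 1 fell adjusted over the list alone, and the median was 0.49 (adjusted p = 0.0246). The adjusted p = 0.643 with an estimated correlation, and the call ended without high-isoflavone replicate 3 (adjusted p = 0.0589), 4 (0.0531) or 5 (0.102). Cyp2c13 rose 1.64-fold (SE 0.13 log2, adjusted p = 0.00496; 0.0549 after centring and scaling). Interferon response genes were lower as a list: none of the 19 passed, alone or over the list, 16 lay below 0 and the median was -0.35 (adjusted p = 0.00221). The adjusted p = 0.674 with an estimated correlation, and 0.0794 with the preset one without high-isoflavone replicate 1. Gbp2, a guanylate-binding protein, differed by -0.64 (SE 0.21, adjusted p = 0.114) and Stat2, a transcription factor of interferon signalling, by -0.41 (SE 0.141, adjusted p = 0.130). Fatty acid oxidation was not called here: none of 29 passed and the median was 0.05 (adjusted p = 0.708), and Hadh differed by 0.25 (SE 0.0743, adjusted p = 0.0758).

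Other large changes on the 1:1 high-isoflavone diet included Edil3, 3.29-fold up (SE 0.287 log2, adjusted p = 0.00251), Cdcp1, a membrane glycoprotein, 3.36-fold up (SE 0.354, adjusted p = 0.0109) with another probe set at 0.30 (adjusted p = 0.238), and Sult1c2a, a sulfotransferase, 3.12-fold up (SE 0.32, adjusted p = 0.00845). Mt1, a metallothionein, rose 2.39-fold (SE 0.267, adjusted p = 0.0142; 0.0518 without high-isoflavone replicate 2). Fabp5, a fatty acid binding protein, fell by 2.31 (SE 0.32, adjusted p = 0.000519), Fabp2 by 1.70 (SE 0.181, adjusted p = 6.98e-05), Ddhd1 by 1.89 (SE 0.232, adjusted p = 0.000181) and Sub1, a transcription coactivator, by 1.60 (SE 0.188, adjusted p = 0.000129), although its other probe set differed by -0.50 (adjusted p = 0.211). Irs3, an adaptor of the insulin receptor, fell by 2.22 (SE 0.484, adjusted p = 0.0171; 0.0561 without casein replicate 5 and also without the 2 higher-floor arrays). In amino acid and glucose metabolism, Hal, which breaks down histidine, rose 1.60-fold (SE 0.134, adjusted p = 0.00978) and Pklr, liver pyruvate kinase, fell by 0.81 (SE 0.155, adjusted p = 0.00762). Neither list was called (amino acid breakdown 1 of 39 up and 1 down, 7 up and 2 down adjusted over the list alone; glucose 2 of 16 up and 1 down, 3 up and 1 down adjusted over the list alone).

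In all, 613 probe sets passed limma's test, 317 higher (51.7%) and 296 lower, with a median size of 0.66, and 4641 had an unadjusted p under 0.05. The rats of the 2 diets did not overlap in 1234 probe sets, 4.45%, where chance gives 0.794%. After quantile normalization 235 were higher and 374 lower (38.6% higher), and after centring and scaling 180 and 471 (27.6%), again with no called probe set changing sign. The count was 338 and 342 without casein replicates 4 and 5, 296 and 331 without high-isoflavone replicates 2 and 4, and, in choices made after seeing the data, 312 without the 2 arrays with a higher floor and 380 without number 1 of all 4 groups.

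Of the probe sets called against casein, 207 were shared by the conventional and the 1:1 high-isoflavone diet in the same direction, 113 higher and 94 lower, and 0 in opposite directions. They included probe sets of Pnpla3, Fabp2, Edil3 and Gclm. Independent lists of these sizes would share 3.22 higher and 1.84 lower. Unchanged groups against the same casein arrays shared 0 in each of 100 simulations. That count decides nothing about the 207, since groups without a diet effect leave hardly any calls to share. Because both comparisons use the same casein rats, the casein arrays were split between them in 20 ways, which left 15.5 shared on average (from 0 to 27) with fewer controls in each comparison. Across probe sets, which are not independent replicates, the differences correlated with r = 0.72 against 0.476 in the simulations, and with r = 0.406 on average with the casein arrays split. Their covariance was 0.0523 against 0.0168 simulated, an excess of 0.0355, and 0.0362 with the casein arrays split.

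The 3:1 high-isoflavone diet asked whether a smaller share of soybean changed the liver relative to casein. Few genes passed. Wfdc21, a protein with a whey acidic protein domain, fell by 1.73 (SE 0.252, n = 5 per diet, adjusted p = 0.0107). The call ended without casein replicate 5 (adjusted p = 0.0601), without the 2 higher-floor arrays (0.0776) and with only the compared arrays (0.058). Fabp2 fell by 1.21 (SE 0.181, adjusted p = 0.0107), and lost its call without casein replicate 5 (adjusted p = 0.0601) or replicate 4 of the 3:1 diet (0.0637), and without the 2 higher-floor arrays (0.0945). Cox7b2, a subunit of cytochrome oxidase, fell by 0.80 (SE 0.0977, adjusted p = 0.00143), from 5.32 ± 0.119 to 4.52 ± 0.218, and kept its call in all settings tried.

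The other named genes were less firm. Cox7b fell by 0.84 (SE 0.144, adjusted p = 0.0367), Car3 rose 1.87-fold (SE 0.165 log2, adjusted p = 0.0492), Car8 rose 1.69-fold (SE 0.132, adjusted p = 0.0385), Ddah1, which breaks down methylarginines, rose 1.62-fold (SE 0.114, adjusted p = 0.0317) and Slc6a13, a GABA transporter, rose 1.58-fold (SE 0.12, adjusted p = 0.0492). In the 20 omissions of a single array, the calls ended 8 times for Cox7b, 14 for Car3, 10 for Car8, 6 for Ddah1 and 14 for Slc6a13, with adjusted p of up to 0.101, 0.158, 0.107, 0.101 and 0.144. Centring and scaling ended the calls of Cox7b (adjusted p = 0.0657), Car3 (0.267), Car8 (0.0619), Ddah1 (0.0567) and Slc6a13 (0.0619), and all 5 ended in further settings too. Of the 4 probe sets of Eprs1, a tRNA synthetase gene named after its values were seen, 1 fell by 1.13 (SE 0.199, adjusted p = 0.0385), and its call ended in 10 of these omissions (adjusted p up to 0.151) and in other settings, among them the compared arrays alone (0.12). The other 3 differed by -0.14, -0.74 and -0.06 and did not pass.

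No member of a list passed over all genes in this comparison. Lipogenesis was lower with a median of -0.55 (1 higher and 11 lower adjusted over the list alone, 20 of 22 below 0, adjusted p = 3.94e-15), and cholesterol genes with a median of -0.21 (4 lower adjusted over the list alone, 17 of 20 below 0, adjusted p = 7.24e-07). These were adjusted p = 0.354 and adjusted p = 0.443 with an estimated correlation. Pgd differed by -0.93 (SE 0.204, adjusted p = 0.119), Acss2 by -0.80 (SE 0.176, adjusted p = 0.119) and Tm7sf2 by -0.73 (SE 0.175, adjusted p = 0.158). NRF2 targets had a median of 0.17 (5 of 19 higher adjusted over the list alone, adjusted p = 0.00752) and male-predominant genes of 0.53 (5 of 9 higher adjusted over the list alone, adjusted p = 0.00202), with adjusted p = 0.537 and adjusted p = 0.443 with an estimated correlation. Gstm3, a glutathione transferase, differed by 1.11 (SE 0.26, adjusted p = 0.151) and Cyp2c13 by 0.58 (SE 0.13, adjusted p = 0.122). Interferon genes had a median of -0.21 (0 of 19 adjusted over the list alone, adjusted p = 0.00687), which ended without casein replicate 1 (adjusted p = 0.0630), and adjusted p = 0.755 with an estimated correlation.

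In limma's test 11 probe sets passed, 6 higher (54.5%) and 5 lower, with a median size of 0.90, and 2249 had an unadjusted p under 0.05. Of these 11, 2 had no single gene symbol. The rats did not overlap in 501 probe sets, 1.81%, where chance gives 0.794%. After quantile normalization 7 passed (2 higher and 5 lower, 28.6% higher) and after centring and scaling 6 (1 higher and 5 lower, 16.7%). The count was 26, 4, 4 and 1 without casein replicates 1, 2, 4 and 5, 4 without conventional soybean replicate 2, 7, 3 and 2 without replicates 1, 3 and 4 of the 3:1 diet, and 7 without replicate 3 of the 1:1 high-isoflavone diet.

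**Figure D2:**
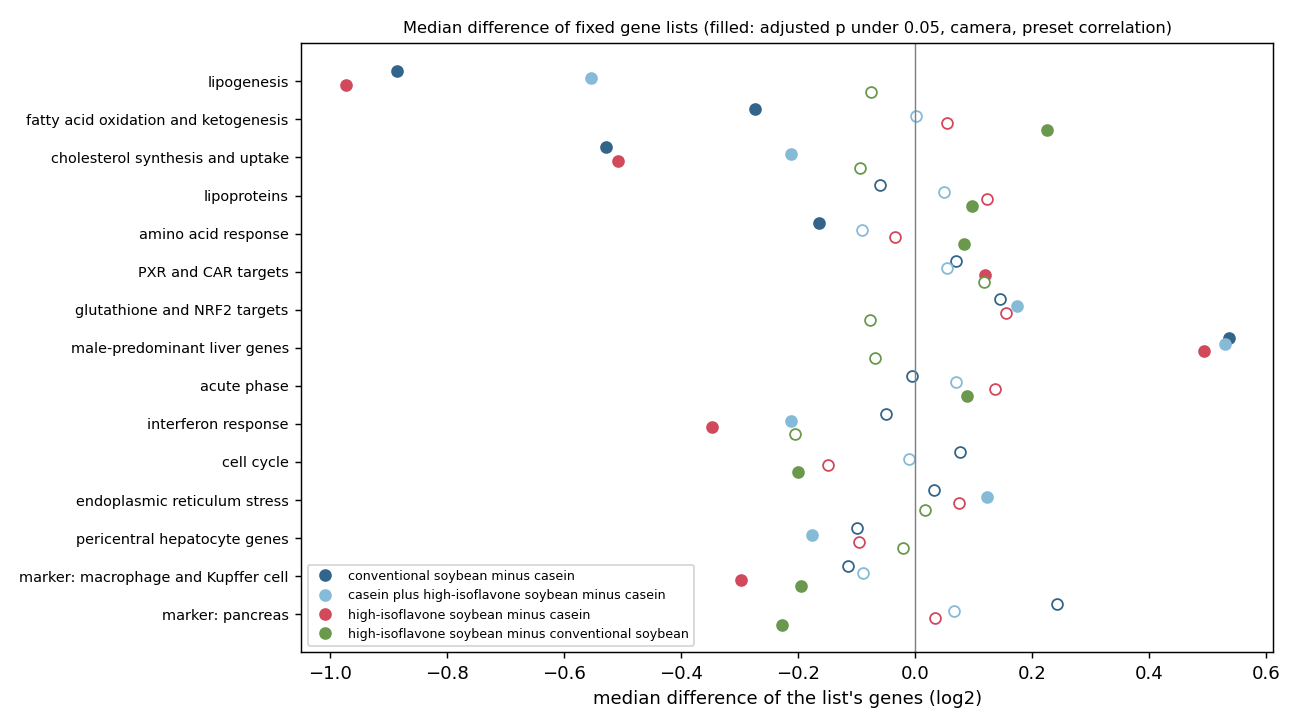
Median log2 difference (horizontal axis) of 15 gene lists (vertical axis) in 4 comparisons of diets. Filled marks are lists past an adjusted p of 0.05 with the preset correlation; lipogenesis was lower in each soybean diet against casein, with medians of -0.89, -0.55 and -0.97, calls that were lost with an estimated correlation (adjusted p = 0.108, 0.354 and 0.0764).

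The high-isoflavone and the conventional soybean were compared at the same share of protein. Isoflavone content cannot be told apart here from any other difference between the cultivars. Chance is not excluded for the 21 calls, since a split of the same rats that did not follow the diet gave 190. Each of the 21 called probe sets was lower on the high-isoflavone diet. Polr2k, a small subunit shared by the RNA polymerases, fell by 1.14 (SE 0.149, n = 5 per diet, adjusted p = 0.00238), from 4.82 ± 0.129 on conventional soybean to 3.68 ± 0.305. Cox7b2 fell by 0.91 (SE 0.0977, adjusted p = 0.000168) and Cox7b, another subunit of cytochrome oxidase, by 1.04 (SE 0.144, adjusted p = 0.00279). Trappc2b, of the vesicle tethering complex, fell by 1.33 (SE 0.207, adjusted p = 0.00767) and Sub1 by 1.25 (SE 0.188, adjusted p = 0.00645), whose other probe set differed by -0.24 (adjusted p = 0.870). For all of these the 5 rats of one diet did not overlap the 5 of the other.

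Further genes that fell were Timm8b, of mitochondrial protein import, by 1.04 (SE 0.165, adjusted p = 0.00767), Rpa3, the small subunit of replication protein A, by 1.0 (SE 0.158, adjusted p = 0.00767), 4930522L14Rikl by 1.31 (SE 0.182, adjusted p = 0.00279) and Rbis, a ribosome biogenesis factor, by 0.89 (SE 0.154, adjusted p = 0.0173). The call for Rbis ended in 5 of the 20 omissions of a single array, with an adjusted p of up to 0.0693. Slirp, a mitochondrial RNA-binding protein, fell by 1.06 (SE 0.166, adjusted p = 0.00767), while its other probe set differed by 0.05 (adjusted p = 0.975). Without number 1 of all groups 9 of the 21 called probe sets kept their call, and the calls of Timm8b (adjusted p = 0.0868), Rpa3 (0.0535), Rbis (0.111) and Slirp (0.0551) ended. With only the compared arrays that of Timm8b ended too (0.055). Named after their values were seen, Rpl26, a ribosomal protein, fell by 0.87 (SE 0.149, adjusted p = 0.0161), Cetn3, a centrin, by 0.63 (SE 0.109, adjusted p = 0.0173), Cox6c by 0.59 (SE 0.108, adjusted p = 0.0305), Atp5mk, of ATP synthase, by 0.55 (SE 0.103, adjusted p = 0.0310) and Eml4 by 0.74 (SE 0.138, adjusted p = 0.0352), whose other 2 probe sets differed by -0.01 and 0.02. Omission of 1 array at a time ended these 5 calls in 2, 4, 7, 8 and 10 of 20 cases, with adjusted p of up to 0.0690, 0.0798, 0.123, 0.124 and 0.142. Centring and scaling ended the calls of Rpl26 (adjusted p = 0.169), Cetn3 (0.0689), Cox6c (0.219), Atp5mk (0.219) and Eml4 (0.0786) as well. With only the compared arrays these 5 calls ended too, at adjusted p = 0.0785, 0.14, 0.127, 0.127 and 0.0923. Leaving out number 1 of all groups ended those of Rpl26 (0.0868), Cetn3 (0.125), Cox6c (0.177) and Atp5mk (0.192), and further settings ended some of the 5. The probe set counts were 21 lower and 0 higher in limma's test, of which 6 had no single gene symbol, with 1959 at an unadjusted p under 0.05. The rats did not overlap in 387 probe sets, 1.4%, where chance gives 0.794%. The count was 13 after centring and scaling, 13 and 11 without conventional soybean replicates 3 and 4, and 12 and 11 without high-isoflavone replicates 1 and 2.

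**Figure D3:**
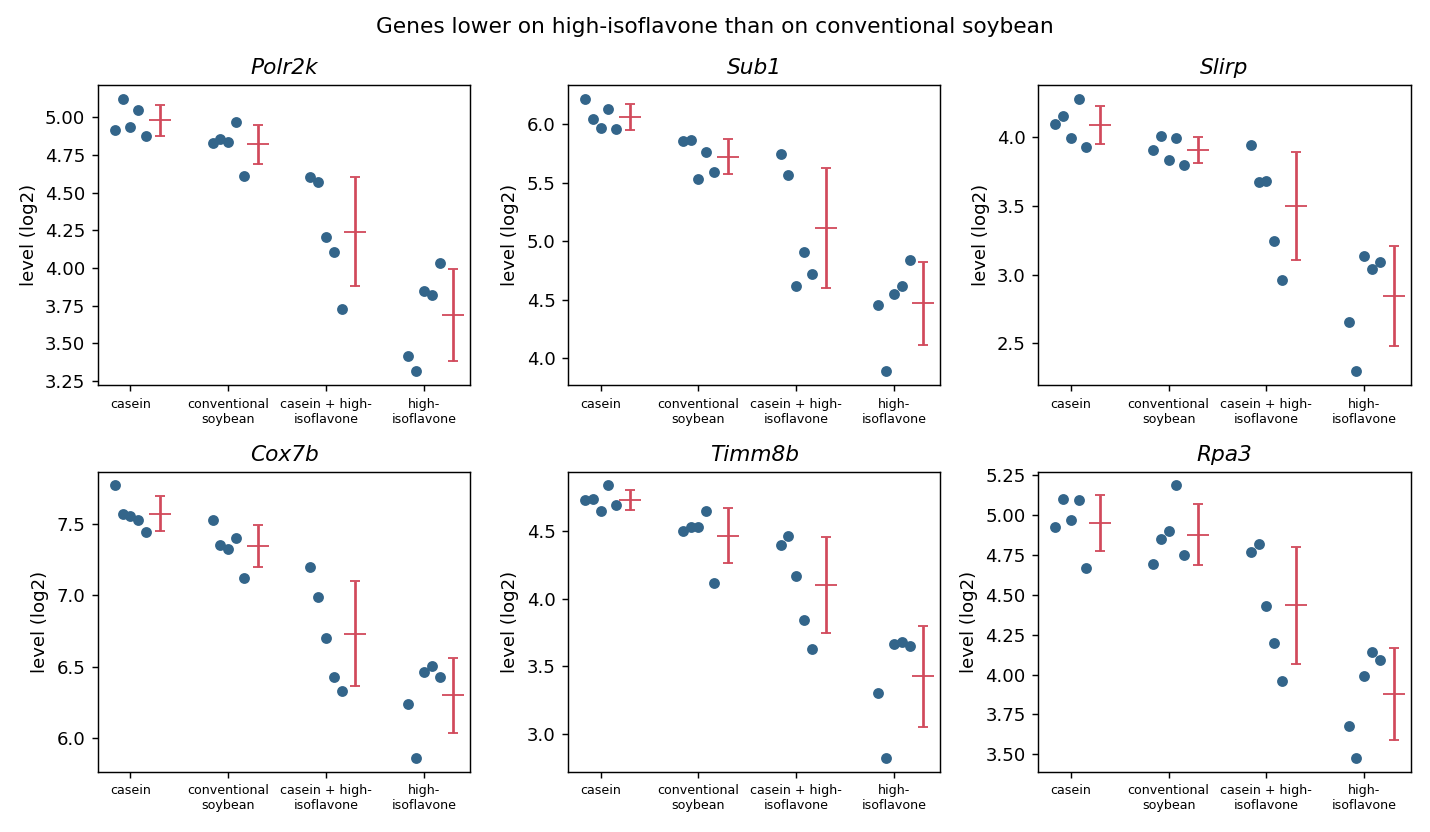
Levels of 6 genes called lower on the 1:1 high-isoflavone than on the conventional soybean diet (vertical axis, log2 signal) for the 4 diets (horizontal axis). Each dot is 1 rat and the red marks are the mean ± SD of 5 rats; Polr2k was at 4.82 on conventional soybean and 3.68 on the 1:1 high-isoflavone diet.

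No member of a fixed list passed over all genes between the cultivars. Fatty acid oxidation genes lay higher on the high-isoflavone diet as a list: 28 of 29 were above 0, 11 rose adjusted over the list alone, and the median was 0.23 (adjusted p = 9.35e-15). The adjusted p = 0.229 with an estimated correlation. Cpt2, of the mitochondrial carnitine shuttle, differed by 0.53 (SE 0.124, adjusted p = 0.150) and Cyp4a3, a fatty acid hydroxylase, by 0.84 (SE 0.226, adjusted p = 0.260). Lipogenesis and cholesterol genes were not called between the cultivars. The mean lipogenesis level per rat differed by -0.12 (SE 0.254, two-sided exact permutation p = 0.619, a test chosen after seeing the data). Atf5, of the amino acid response list, differed by 0.42 (SE 0.0876, adjusted p = 0.0780).

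The last questions concerned the share of high-isoflavone soybean. Between the 1:1 and the 3:1 diet 0 probe sets passed limma's test, with 2000 at an unadjusted p under 0.05 and a smallest adjusted p of 0.368. Quantile normalization and centring also gave 0, and 1 passed without replicate 4 or without replicate 5 of the 3:1 diet. The rats did not overlap in 316 probe sets, 1.14%, where chance gives 0.794%. The genes with the smallest p, all at an adjusted p of 0.368, were Pmvk, -0.94 (SE 0.17), Ddhd1, -1.22 (SE 0.232), Orm1, an acute phase protein, 0.74 (SE 0.158), Cnn3, a calponin, 0.54 (SE 0.112), and Ephx2, soluble epoxide hydrolase, 2.48 (SE 0.52).

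As lists, cholesterol genes were lower on the 1:1 than on the 3:1 diet (20 of 20 below 0, 1 lower adjusted over the list alone, median -0.30, adjusted p = 8.76e-09), and so was lipogenesis (21 of 22 below 0, 3 lower adjusted over the list alone, median -0.31, adjusted p = 2.8e-06). The adjusted p = 0.655 and adjusted p = 0.677 with an estimated correlation. Macrophage markers moved with them (10 of 12 below 0, 0 adjusted over the list alone, median -0.23, adjusted p = 0.0124). That adjusted p = 0.943 with an estimated correlation, and the call ended without replicate 4 of the 3:1 diet (adjusted p = 0.0885) or high-isoflavone replicate 3 (0.0735). No probe set departed from a straight line over casein, the 3:1 and the 1:1 diet (0 in limma's test, 1202 at an unadjusted p under 0.05, smallest adjusted p 0.313). It was 1 without conventional soybean replicate 4 and 1 without replicate 5 of the 3:1 diet.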

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

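The values of this part are single rats that stood apart within their diet, and no test reported here was chosen after its result was seen, although Rpl26 was named after its values were seen. In each group of 5 rats, the highest or lowest value was marked when its gap to the nearest other rat exceeded 0.71 of the range of the group. This held in 18 of 235 groups examined, where chance marks about 1 in 20 groups, or 11.8 here. All values are log2 signals.

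On conventional soybean, replicate 3 was the lowest for Aldh1b1 (1.10, nearest other rat 3.0), Fads2 (5.05, nearest 5.76) and Pmvk (3.94, nearest 4.35). It was thus low in 3 of the genes that fell on that diet. Replicate 5 of this diet was the lowest for Timm8b (4.12, nearest 4.51). On casein, replicate 1 was the lowest for Pgd (5.78, nearest 6.28), Sc5d (5.89, nearest 6.15) and Commd6 (3.65, nearest 5.07), and replicate 4 was the lowest for Hadh (7.27, nearest 7.57).

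On the 1:1 high-isoflavone diet, replicate 3 was the highest for Pgd (5.35, nearest 4.85) and Cyp51 (6.15, nearest 5.88), and replicate 5 for Fabp2 (2.33, nearest 1.84). Replicate 2 was the lowest for 4930522L14Rikl (0.856, nearest 1.51) and Rpl26 (6.66, nearest 7.27), and replicate 1 for Apoa4 (8.59, nearest 9.11).

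On the 3:1 high-isoflavone diet, replicate 4 was the highest for Car8 (5.37, nearest 4.73) and the lowest for Pmvk (3.98, nearest 4.76). Ephx2 was at 4.82 in replicate 5 and at most at 2.43 in the other 4 rats of this diet. Replicate 1 of this diet, one of the arrays with a higher floor, had the highest difference between the 3′ and 5′ signals of beta-actin (2.13, nearest 1.56).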

How the results depend on the processing

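The tests chosen only after the result was seen are the omissions of the 2 arrays with a higher floor and of number 1 of all 4 groups, and the term for number 1. The setting log2(value + 32) was not applicable, since the deposited values were logs already. No named gene and no called list reversed. Of 4140 values of 130 named results under the alternatives, 3546 kept their side of the threshold, 582 lost and 12 gained it, and 50 of 111 named calls held in every setting applied. The minimum of 1.5-fold was not applied to these named results. Leaving the omissions of single arrays and the 1.5-fold minimum aside, 27 of 46 named calls for conventional soybean against casein, 2 of 9 for the 3:1 diet, 33 of 41 for the 1:1 diet and 9 of 15 between cultivars held in every other setting fixed beforehand. Except where given, the cause was not tested.

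A minimum of 1.5-fold, which drops small changes by construction, left 269 calls of 453 for conventional soybean against casein and 375 of 613 for the 1:1 high-isoflavone diet. Without the higher-floor arrays these were 114 and 312, and the 3:1 diet gave 4 instead of 11. Without number 1 of all groups the 1:1 diet gave 380, the 3:1 diet 6, and high-isoflavone against conventional soybean 13 instead of 21. The 3:1 diet gave 7 after quantile normalization, 6 after centring and scaling, 18 and 19 without the dimmest probe sets (fewer tested), 3 without the trend, 25 with array weights and 5 with only the compared arrays. High-isoflavone against conventional soybean gave 13 after centring and scaling and 12 with only the compared arrays. Quantile normalization kept 359 of the 453 calls, 522 of 613, 7 of 11 and 19 of 21.

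With 1 array left out the counts ran from 120 to 499 for conventional soybean against casein, 1 to 26 for the 3:1 diet, 296 to 716 for the 1:1 diet, 11 to 31 between cultivars, 0 to 1 between the shares of high-isoflavone soybean and 0 to 1 for the departure from a line. Fewer arrays lower the power, and the rest was not tested. Called lists ran from 5 to 8 for conventional soybean (8 without its replicate 3). Between cultivars they ran from 3 to 9 against 7 (3 without conventional soybean replicate 4, 4 without high-isoflavone replicate 2). Between the 2 shares they ran from 2 to 7 against 3 (7 and 5 without replicates 1 and 4 of the 1:1 diet).

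With an estimated correlation 0 lists passed in any of the 5 comparisons, where the preset one gave 5, 7, 6, 7 and 3, since it allows for genes that move together. In 1 direction fry called 4, 0, 4, 0 and 0 lists, and in either direction 11, 5, 12, 1 and 0. Splitting the casein arrays left 15.5 shared calls of 207, with fewer controls in each comparison.

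With the replicate number as a block, the 3:1 diet gave 23 calls instead of 11, and the other counts were 591, 659 and 23, with 0 between the shares. As a whole the numbers do not pair the rats. Of 30 pairs with a shared number, 12 correlated over 0.1 (from -0.163 to 0.401), and 7 of 20 arrays correlated best with their own number. Pairs of number 1 ran from 0.203 to 0.401, against a median of -0.00585 among pairs of numbers 2 to 5. The arrays of number 1 thus shared a structure across the diets, whose source was not tested. The block ended the call of PXR and CAR targets on the 1:1 diet (adjusted p = 0.0504), as did leaving out the dimmest probe sets (0.0715), over a range of up to 0.266. The mean of all probe sets of a gene ended that of macrophage markers between cultivars (adjusted p = 0.0628). With a term for number 1, conventional soybean against casein gave 618 calls and the 1:1 diet against casein 757.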

Other observations

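The tests of feeding state, of the authors' normalization and of other cell types, the mean list level per rat, the short respiratory chain list as a condition for loss of short RNAs, and the splits for the 2 shares of high-isoflavone soybean and for the departure from a line were chosen only after the result was seen.

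Between the cultivars, several further lists shifted with small differences and no member past the threshold over all genes. Cell cycle genes were lower on the high-isoflavone diet with a median of -0.20 (23 of 31 below 0, 0 adjusted over the list alone, adjusted p = 0.00781), and macrophage markers with a median of -0.20 (10 of 12 below 0, 0 adjusted over the list alone, adjusted p = 0.0257). Pancreas markers had a median of -0.23 (7 of 7 below 0, 0 adjusted over the list alone, adjusted p = 0.0191). Acute phase genes had a median of 0.09 (16 of 18 above 0, 0 adjusted over the list alone, adjusted p = 0.00668), lipoproteins of 0.10 (13 of 16 above 0, 0 adjusted over the list alone, adjusted p = 0.00668) and the amino acid response of 0.08 (16 of 24 above 0, 1 higher adjusted over the list alone, adjusted p = 0.0191). With an estimated correlation these 6 had adjusted p = 0.572, 0.712, 0.229, 0.229, 0.229 and 0.293. Left-out arrays ended each call: cell cycle without conventional soybean replicate 4 (adjusted p = 0.235) or high-isoflavone replicate 2 (0.0596), acute phase without conventional soybean replicate 4 (0.0519), lipoproteins without high-isoflavone replicate 5 (0.0947), and pancreas without conventional soybean replicate 4 (0.0660) or high-isoflavone replicate 4 (0.0632) or 5 (0.0867). The amino acid response lost its call without conventional soybean replicate 3 (0.0688) or 4 (0.0823) or high-isoflavone replicate 1 (0.0987) or 2 (0.0508), and macrophage markers without conventional soybean replicate 2 (0.0695) or 3 (0.755) or high-isoflavone replicate 1 (0.0547), 2 (0.0508) or 3 (0.0828). Quantile normalization ended the calls of lipoproteins and acute phase (adjusted p = 0.227 for both).

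On the 3:1 diet against casein, endoplasmic reticulum stress genes had a median of 0.12 (15 of 18 above 0, 1 higher adjusted over the list alone, adjusted p = 0.0187) and pericentral genes of -0.18 (8 of 10 below 0, 0 adjusted over the list alone, adjusted p = 0.0261), with adjusted p = 0.674 for both with an estimated correlation. The first call ended without casein replicate 2 (0.127) or 5 (0.112) or replicate 2 (0.104) or 4 (0.0640) of the 3:1 diet. The second ended without casein replicate 2 (0.0552), 3 (0.0503) or 4 (0.0589) or replicate 1 (0.0724), 2 (0.197) or 3 (0.120) of the 3:1 diet. Single genes also changed on soybean in lists that were not called in the same comparison. Baat, which joins bile acids to amino acids, rose 1.40-fold on the 1:1 high-isoflavone diet against casein (SE 0.102 log2, adjusted p = 0.0141), Kif11, a mitotic kinesin, 2.07-fold (SE 0.223, adjusted p = 0.0144) and Sel1l, of protein degradation in the endoplasmic reticulum, 1.59-fold (SE 0.0949, adjusted p = 0.000618), while Epcam, an adhesion molecule of bile duct cells, fell by 0.95 (SE 0.158, adjusted p = 0.00251). After centring and scaling Baat differed by 0.31 (adjusted p = 0.244), against 0.48 as deposited, and Kif11 lost its call with only the compared arrays (0.0516), without the 2 higher-floor arrays (0.0559) and without number 1 of all groups (0.0564). The smallest adjusted p of the uncalled lists over the 5 comparisons were 0.052 for bile acid synthesis, 0.246 for amino acid breakdown, 0.0923 for glucose metabolism, 0.662 for AhR targets, 0.586 for female-predominant genes, 0.662 for the growth hormone axis, 0.586 for clock genes and 0.357 for periportal genes. For markers they were 0.521 for endothelial cells, 0.586 for stellate cells, 0.772 for bile duct cells, 0.174 for lymphocytes and 0.121 for neutrophils. Median, mean and test had the same sign in every called list, while in some uncalled ones they did not, such as lipoproteins on the 1:1 diet against casein (median 0.12, mean -0.01, adjusted p = 0.927) and AhR targets on the 3:1 diet (median 0.12, mean -0.11, adjusted p = 0.806).

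Ephx2 was low in all rats of the 3:1 diet but replicate 5, at 1.74, 2.17, 2.43 and 2.04 against 4.82, and also in conventional soybean replicate 4, at 2.03. The other 14 rats of the remaining diets were between 4.15 and 5.97 (log2). No explanation was tested.

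Polr2k, Cox7b, Timm8b and Rpa3, which were lower on the high-isoflavone than on the conventional soybean diet, encode small proteins, and loss of short RNAs in sample preparation is a candidate explanation. RNA lengths and the share of short genes among the called ones were not measured. A list of short nuclear and cytosolic genes, which left out the called genes, was lower by a mean of -0.135 (SE 0.0494, 34 of 38 measured, two-sided exact permutation p = 0.0397). But a list of short respiratory chain genes, which held none of the called genes either, differed by -0.0533 (SE 0.0475, 21 of 37 below 0, exact permutation p = 0.31). Long nuclear and cytosolic genes differed by 0.0655 (SE 0.0434, 6 of 26 below 0, exact permutation p = 0.135), so loss of short RNAs stays open. A lower respiratory chain as a whole is argued against by its long genes at 0.0117 (SE 0.0554, exact permutation p = 0.833). With any 1 array left out, at least 10 of the 21 called probe sets kept their call, and all 21 kept their direction and an unadjusted p under 0.05. Whether a few arrays carry the pattern still cannot be told, since probe sets chosen for a difference over all arrays tend to keep it without 1 of them, and an effect of the cultivar is open and untested.

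For the lower lipogenesis genes on soybean, the mean of the list per rat differed from casein by -1.0 on conventional soybean (SE 0.232, exact permutation p = 0.00794, the smallest that 5 against 5 can give), -0.69 on the 3:1 diet (SE 0.228, exact permutation p = 0.0159) and -1.13 on the 1:1 diet (SE 0.185, exact permutation p = 0.00794). On the 1:1 diet quantile normalization kept 1.03 of the median difference. It was run on values that the authors had already normalized and cannot undo that step, so their normalization stays open. A higher share of macrophages on the 1:1 diet is argued against by their markers, the lowest of the marker lists compared there, at -0.254 (SE 0.0897, exact permutation p = 0.0397). Macrophage markers differed by -0.058 on conventional soybean (SE 0.167, exact permutation p = 0.81) and -0.0565 on the 3:1 diet (SE 0.088, exact permutation p = 0.571), which decides nothing there. On the 1:1 diet endothelial markers differed by 0.0744 (SE 0.0579), bile duct ones by 0.0704 (SE 0.0973) and stellate ones by -0.0132 (SE 0.0581). A higher share of these other cells stays open, and so does that of macrophages on the other soybean diets. Genes that rise in fasting differed from casein by -0.332 on conventional soybean (SE 0.183, 5 of 7 below 0, exact permutation p = 0.135), -0.14 on the 3:1 diet (SE 0.174, exact permutation p = 0.421) and -0.0212 on the 1:1 diet (SE 0.184, exact permutation p = 0.905), with members on both sides of 0 on each diet, so a more fasted state stays open. Within diets the fasting and lipogenesis means correlated over 20 arrays with r = -0.218 (permutation p = 0.421) and rho = -0.15 (permutation p = 0.569), and r = -0.0504 without the 2 farthest arrays. A dietary effect of soybean remains open, as a hypothesis found and tested on the same rats.

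Other splits of the same rats into equal groups, 100 drawn per comparison, bear on whether chance can give such counts. For the changed probe sets against casein, no other drawn split reached the count of the split by diet. This held for conventional soybean (453, highest other split 1), the 3:1 diet (11, highest other 1) and the 1:1 diet (613, highest other 3). Each gave 1 of 100, the smallest share possible here, since the real split is among the 100. Chance alone is thus unlikely to give these counts, although the comparisons share the same casein rats and are not independent. The 3:1 count also fell to 1 without casein replicate 5. Between the cultivars 2 of 100 splits gave 21 or more, the real one included. Chance is not excluded there, since the highest other split gave 190, more than the split by diet. That split set conventional soybean replicates 1, 3 and 5 with high-isoflavone replicates 1 and 2 against the rest, which points to a structure among these rats that does not follow the diet. It followed the main axis of variation over all arrays (first principal component, 14.2% of the variance). The first set lay at -10.4 or lower on this axis and the rest at -5.36 or higher. Casein rats ran from -12.1 to 25.2 on it and rats of the 3:1 diet from -21.6 to 20.9. The structure is therefore not limited to the soybean cultivars, and its source was not tested. For the 2 shares of high-isoflavone soybean (0, highest other 3) and the departure from a line (0, highest other 18), the splits decide nothing about chance, since every split gives at least 0. For the counts of called lists chance cannot be excluded: 55 of 100 splits gave 5 or more for conventional soybean (highest other 10), 9 gave 7 or more for the 3:1 diet (highest other 9), 17 gave 6 or more for the 1:1 diet (highest other 7), 24 gave 7 or more between cultivars (highest other 13) and 53 gave 3 or more between the shares (highest other 9).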
